A study of Arabidopsis thaliana with 18 samples.

How the data were processed

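RNA from whole Arabidopsis thaliana plants was measured on 18 single-colour Affymetrix Arabidopsis Gene ST arrays, which report a summarised signal for each probe set, a group of short probes. Per the labels, plants 4 weeks old were grown in short days, sprayed with 250 µM methyl jasmonate (MeJA, a volatile form of the wound and defence hormone jasmonate) or with a mock solution, and harvested 3 h later. Each sample pooled several plants, per the labels. Groups and replicate numbers were taken from the sample titles, and every group name below is the label of its arrays. The labels do not say whether the pools of a group were grown separately, so p-values measure the spread between these pools.

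The deposited table holds signal intensity on a linear scale, which the authors made with Affymetrix Expression Console, per the submitters' processing notes. The summarisation method, the software version and the genome build are not given in the sources used here. The linear scale was read from the values, and the array medians lay between 14.87 and 17.5. The design fixed before the data were examined had assumed log2 values and named log2(value + 1) as the fallback for linear ones, which was used throughout.

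The table holds 38408 probe sets. A platform annotation paired 16722 of them with 1 gene, 759 with several genes and 20927 with none, and a probe set without a listed gene is unnamed here rather than without a gene. Symbols were updated through a table of the TAIR10.1 assembly, which matched 16574 of the single-gene probe sets and was used for names only. Probe sets with a signal of at least 50 in any array were kept (14444 probe sets), and the probe set with the highest mean was used for each gene named alone. This left 5689 genes, 833 of them with a symbol. Of the 10 genes that were to be named in every case, PDF1.2a and IAA29 were tested. PHYB, JAZ10, ST2A, VSP2, MYC2, LOX2, PIL1 and ATHB2 were not analysed here because no named probe set was paired with them, so the mutant genes could not serve as a check of the genotype labels.

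A limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 8 groups was fitted to all 18 arrays, so that all groups shared an estimate of the spread with 10 residual degrees of freedom. The 14 contrasts used moderated statistics and Benjamini-Hochberg adjustment over the 5689 genes, with calls at an adjusted p under 0.05. The model was tested on simulated data with 5689 genes, where it recovered 88% of 100 genes changed by 1 on the log2 scale and 99% of those changed by 2 for MeJA in Col, with 4 false calls, and 95% and 100% for MeJA in phyb, with 14 false calls. In the simulation the changed genes were drawn at random, and no array lay on the side of the other treatment. These shares therefore do not describe recovery in the deposited arrays. There the fit called 2 genes for MeJA in jaz10phyb, and 1058 with the same fold changes without 2 phyb arrays described below. The number of arrays, 2 or 3 per group, limits the precision.

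Of 20 gene lists fixed before the data were examined, with 320 genes in all, 54 genes had a named probe set and 32 were tested. Lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the lists of a contrast. These were jasmonate catabolism and sulfation (3 of 12 genes), anthocyanin and flavonoid synthesis (4 of 18), photosynthesis (5 of 33) and abscisic acid and dehydration (3 of 14). The small coverage means that a list result describes those members only. The fry results of these lists are not printed below.

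Genes named were the 10 above, for each contrast up to 6 with the largest rise and 6 with the largest fall among called genes with a symbol whose groups did not overlap, and up to 4 members of each list. Genes outside this rule are said to have been chosen after their values were seen.

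The alternatives fixed beforehand were no filter, a stricter filter, a replicate block, separate fits, other eBayes settings, all probe sets, array centring, quantile normalization, unadjusted p with a fold minimum, a SAM-type statistic for Col, other list tests, and each array left out in turn. After the data were seen, 2 phyb arrays were found on the side of the other treatment. Every result was then also computed without both, with the naming rule applied to that fit too, and each of the other arrays was left out of that fit in turn. Because these arrays were doubted for the very response that is tested, calls made without them are not independent evidence that the response exists in phyb. No array was relabelled.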

Results

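The 18 arrays covered wild-type Col-0, the phyb-9 mutant of the red-light receptor phytochrome B, a mutant of JAZ10, a repressor of jasmonate signalling, and the jaz10 phyb-9 double mutant, each after mock or MeJA spray. There were 3 arrays in each phyb group and 2 in each other group. The design asks whether loss of phytochrome B alters the transcript response to MeJA and whether that depends on JAZ10.

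Treatment set the main axis of variation, with 65.2% of the variance on the first principal component, and phytochrome B genotype the next, with 8.43%. In 2 phyb arrays the treatment position went against the label. A MeJA score was taken as the mean of 246 genes raised minus the mean of 126 genes lowered by MeJA in Col. The array labelled phyb control 2 had a score of 1.52, against -1.12 and -0.785 in the other phyb control arrays. The array labelled phyb MeJA 3 had a score of -0.99, against 1.57 and 0.969 in the other phyb MeJA arrays. Both groups are reported as labelled. The counts of each comparison are given again without these 2 arrays, with the values of some lists and named genes. This choice was made after the data were seen. Leaving them out does not alter the fold changes among Col, jaz10 and jaz10phyb. It changes the shared spread behind their p-values, and so the genes called and selected. The estimated correlations of gene sets change too. They went from 0.981 to 0.584 for the jasmonate catabolism list, and from 0.812 to 0.243 for genes raised in jaz10.

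**Figure D1:**
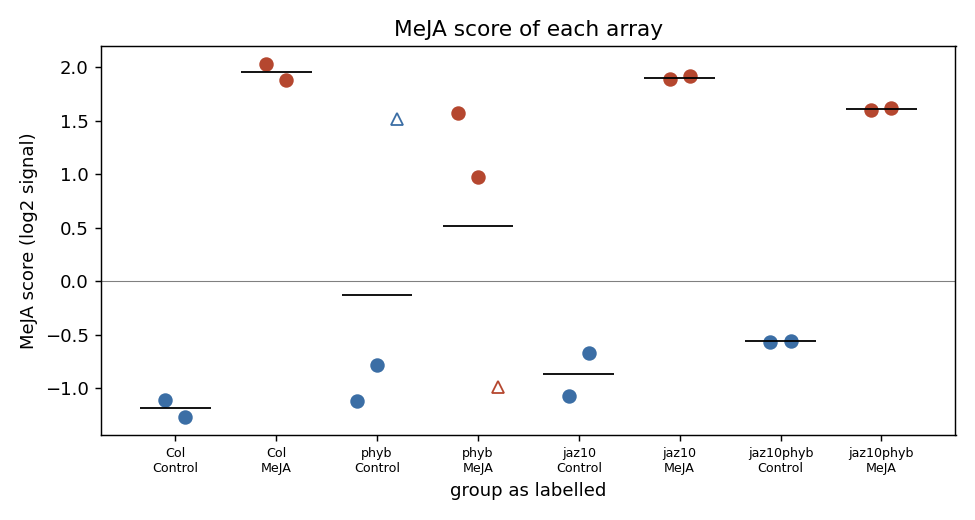
MeJA score of each array (vertical axis, log2 signal) by group as labelled, with control arrays in blue, MeJA arrays in red and group means as lines. Open triangles mark the arrays labelled phyb control 2 (1.52) and phyb MeJA 3 (-0.99), which lay among arrays of the other treatment.

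In Col, the jasmonate oxidases JOX3 (AT3G55970), JOX4 (AT2G38240) and JOX2 (AT5G05600), which inactivate the hormone, rose by 4.23 ± 1.04 (SE, here and below, log2 scale, n = 2 arrays per group), 3.25 ± 0.69 and 2.58 ± 0.71. JMT, which methylates jasmonate, rose by 3.48 ± 0.85 and BSMT1, a benzoate and salicylate methyltransferase, by 2.85 ± 0.77. In Col control plants the mean log2 signal was 3.58 for JOX3, 3.95 for JOX4, 4.81 for JOX2, 4.44 for JMT and 3.06 for BSMT1, below the signal minimum of 5.67 on this scale. Signal over background was not tested, so the size of these changes is uncertain. The same holds for other genes named here with a group mean below that minimum, among them NAI1, MSRB9, PDF1.2a and EXPA8 in Col (3.07, 4.01 and 4.73 in control plants, 3.47 after MeJA). CSLA01 (4.37 ± 1.15), 4CL8 (3.75 ± 1.13), MSRB9 (3.65 ± 0.85) and NAI1, a regulator of endoplasmic reticulum bodies (3.56 ± 0.95), also rose. OPCL1, a jasmonate synthesis enzyme, rose by 1.52 ± 0.33 and the defensin PDF1.2a by 1.74 ± 0.51. EXPA8, a wall-loosening expansin, changed by -3.72 ± 0.98, and BZIP61, ATSPS4F, BZIP34, DRT100 and UGT85A5 fell by between 2.38 and 1.77. All 3 tested members of the jasmonate catabolism list rose, over all genes and adjusted over the list alone, with a median of 3.25 (camera adjusted p = 0.00698; adjusted p = 0.383 with an estimated correlation, and 0.041 without the 2 doubtful arrays). The lists for anthocyanin (median 0.661), photosynthesis (-0.163, 1 of 5 members lower) and abscisic acid (0.142) did not pass. In limma, 468 genes were higher and 369 lower of 5689. The count was 1771 without the 2 doubtful phyb arrays and 1417 without phyb control 2 alone. The 1771 became 1119 without Col MeJA 2. The count of 837 lay between 0 and 6 when any of the 4 Col arrays was left out, and between 473 and 549 without any jaz10 MeJA or jaz10phyb array.

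In jaz10, MSRB9 rose by 4.17 ± 0.85, JOX4 by 3.72 ± 0.69, TBL37 by 3.14 ± 0.78, CYP71B37 by 2.96 ± 0.84, FLR1 by 2.77 ± 0.71, MSRB6 by 2.55 ± 0.7 and IRX15-L by 2.38 ± 0.64 (n = 2 arrays per group). BZIP34, BZIP61, BGLU47, DRT100, CRR21 and the dehydrin COR47 fell, COR47 by 1.24 and BZIP34 by 2.16. Among anthocyanin genes, the dihydroflavonol reductase DFR rose by 1.29 ± 0.33, UGT79B1 by 1.72 ± 0.36 and UGT75C1 by 0.95 ± 0.23, 3 of 4 members over all genes and adjusted over the list alone (list median 1.12, camera adjusted p = 0.000654; adjusted p = 0.138 with an estimated correlation). The jasmonate catabolism list had a median of 3.53, with 1 of 3 members called over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00103; adjusted p = 0.138 with an estimated correlation, and 0.0273 without the 2 doubtful arrays). In limma, 251 genes were higher and 246 lower. The count was 1400 without the 2 doubtful phyb arrays, 1026 without phyb control 2 alone and 978 without phyb MeJA 3 alone. The 1400 became 801, 868 and 932 without jaz10 control 1, MeJA 1 and MeJA 2. The count of 497 lay between 0 and 42 when any jaz10 array was left out, and between 83 and 104 without any Col or jaz10phyb array. Of the genes called in Col, 162 higher and 82 lower ones were also called in jaz10, against 20.65 and 15.96 for independent lists. Without the 2 doubtful arrays these were 464 and 553, against 86.6 and 132.9. In limma no gene passed the test of a different response in jaz10 and Col in either fit (331 at an unadjusted p under 0.05 with all arrays, 573 without the 2 arrays). The difference in response had a median of 0.531 for the anthocyanin list (camera adjusted p = 0.0245; adjusted p = 0.292 with an estimated correlation) and of -0.369 for the abscisic acid list (camera adjusted p = 0.0245; adjusted p = 0.183 with an estimated correlation).

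In jaz10phyb, limma called 2 genes with all arrays and 1058 without the 2 doubtful phyb arrays, with the same fold changes. The 2 genes, AT5G01210 (1.05 ± 0.14) and AT5G17010 (-0.66 ± 0.09), have no symbol and were chosen after their values were seen. With all arrays, 1319 genes had an unadjusted p under 0.05, and the count of 2 became 547 without phyb control 2, 528 without phyb MeJA 3, 7 and 4 without phyb control 1 and 3, and 0 without any jaz10phyb array. In the fit without the 2 arrays NAI1 (3.08 ± 0.21), MSRB9 (3.08 ± 0.14), 4CL8 (3.02 ± 0.41), CYP71B37 (2.86 ± 0.3), CSLA01 (2.64 ± 0.35), BSMT1 (2.46 ± 0.23), JOX3 (2.42 ± 0.2), JOX4 (2.25 ± 0.19) and JOX2 (1.59 ± 0.15) rose, and EXPA8, SCPL34, BGLU47, ATSPS4F, BZIP61 and BZIP34 fell by between 1.61 and 1.26 (n = 2 arrays per group). The jasmonate catabolism list had a median of 2.25 (camera adjusted p = 0.00394 with all arrays; adjusted p = 0.198 with an estimated correlation, and 0.0285 without the 2 arrays), with 0 of 3 members called over all genes and 3 adjusted over the list alone. The anthocyanin list had a median of 0.656 (camera adjusted p = 0.00394; adjusted p = 0.198 with an estimated correlation). The 1058 calls became 691 without jaz10phyb control 1 and 635 without jaz10phyb MeJA 2.

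In phyb as labelled, limma called no gene after MeJA among 5689, and 198 had an unadjusted p under 0.05 (n = 3 arrays per group). JOX3 had a log2 change of 0.67 ± 0.85, JOX4 of 0 ± 0.56, CSLA01 of 1.03 ± 0.94 and EXPA8 of -0.68 ± 0.8. The anthocyanin list had a median of 0.276 (camera adjusted p = 0.00579; adjusted p = 0.36 with an estimated correlation), and of 0.61 without the 2 doubtful arrays (adjusted p = 0.214 with an estimated correlation). Without the 2 doubtful arrays (n = 2 arrays per group), 393 genes were higher and 533 lower. In that fit CSLA01 rose by 3.33 ± 0.35, 4CL8 by 3.09 ± 0.41, JOX3 by 2.82 ± 0.2, NAI1 by 2.62 ± 0.21, CHAT, an acyltransferase of leaf volatiles, by 2.6 ± 0.13, JAL23 by 2.57 ± 0.22, JOX2 by 2.05 ± 0.15, BSMT1 by 1.8 ± 0.23 and JOX4 by 1.39 ± 0.19. EXPA8 fell by 2.57, SCPL34 and ATSPS4F by 1.62, BZIP34 by 1.48, BZIP61 by 1.43 and the auxin-responsive IAA29 by 1.36. The jasmonate catabolism list had a median of 0.593 with all arrays (camera adjusted p = 0.295; adjusted p = 0.626 with an estimated correlation), and of 2.05 without the 2 doubtful arrays (camera adjusted p = 1.17e-06; adjusted p = 0.0313 with an estimated correlation). The 926 calls of this fit became 402 without phyb MeJA 1 and 460 without phyb control 1. Of them, 365 higher and 402 lower ones were also called in Col in the same fit, against 58.58 and 86.48 for independent lists. Independent lists, here and for jaz10 above, do not allow for the shared spread. The 2 arrays were also doubted on genes selected in Col, so part of this overlap is built in.

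**Figure D2:**
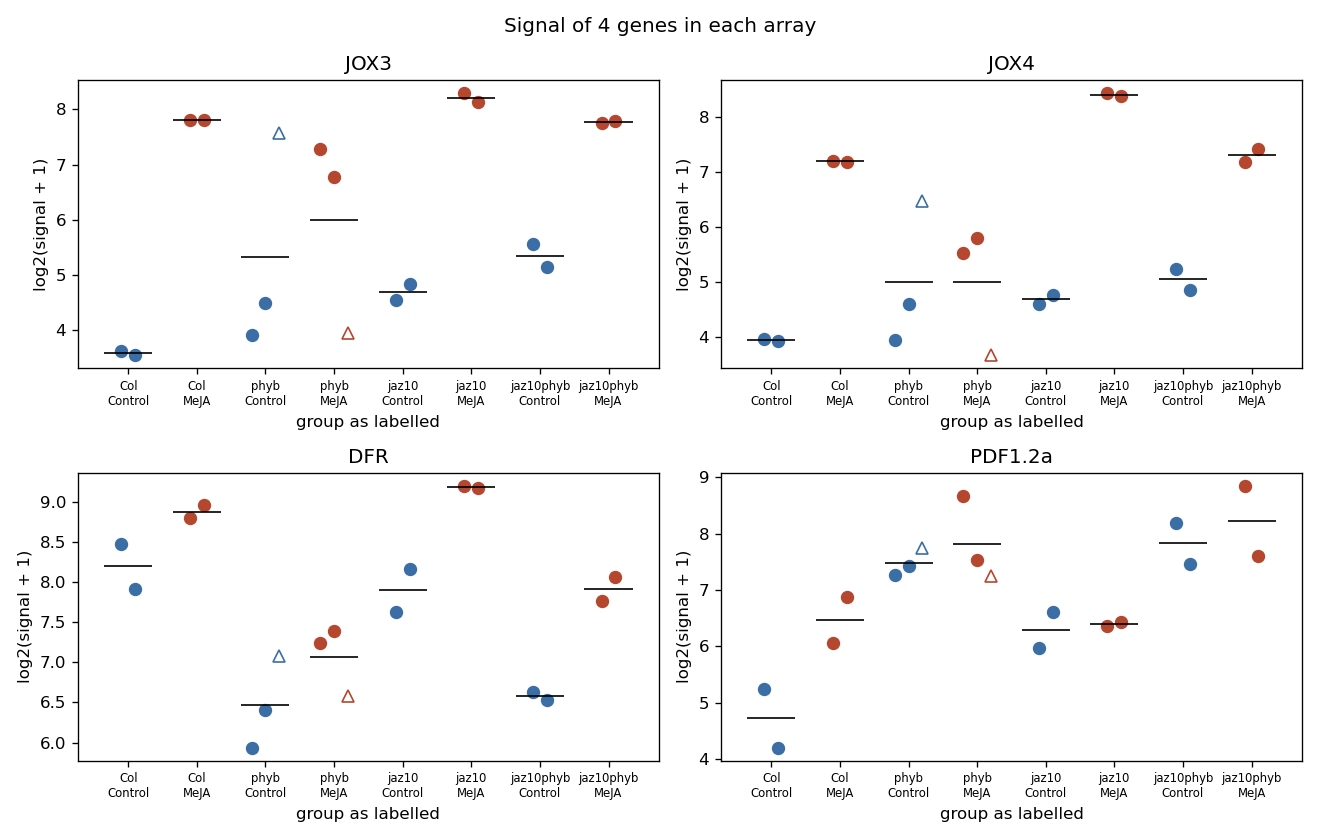
Signal of JOX3, JOX4, DFR and PDF1.2a (vertical axes, log2(signal + 1)) in each array by group as labelled, with control arrays in blue, MeJA arrays in red and group means as lines. Open triangles mark the arrays labelled phyb control 2 and phyb MeJA 3, which for JOX3 and JOX4 lay with arrays of the other treatment. DFR was lower in phyb than in Col in both treatments (-1.72 and -1.8).

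In plants labelled control, the defensin gene PDF1.2a was higher in phyb than in Col by 2.75 ± 0.47 and PDF1.2b by 2.38 ± 0.44 (n = 3 phyb and 2 Col arrays). These near-identical genes may share probes and are uncertain as separate values. The phyb mean includes the doubtful phyb control 2, whose MeJA score was 1.52. Gene values given only with all arrays may therefore not describe mock-sprayed plants alone. The thionin THI2.2 (0.78 ± 0.14) and CSLC04 (0.73 ± 0.13) were higher, and DFR (-1.72 ± 0.3), the signal peptide gene CLE41 (-1.02 ± 0.15) and NDC1 (-0.65 ± 0.12) were lower. The anthocyanin list had a median of -0.975, with 1 of 4 members called over all genes and 3 adjusted over the list alone (camera adjusted p = 2.49e-05; adjusted p = 0.0949 with an estimated correlation, and 0.0262 without the 2 doubtful arrays). For jasmonate catabolism the median was 1.06 (camera adjusted p = 0.0382; adjusted p = 0.228 with an estimated correlation), and it was 0.329 without the 2 arrays (adjusted p = 0.159 with an estimated correlation). The photosynthesis list had a median of -0.0793 (camera adjusted p = 0.0382; adjusted p = 0.228 with an estimated correlation) and did not pass without the 2 arrays (camera adjusted p = 0.148). IAA29 differed by 1.28 ± 0.5 (limma adjusted p = 0.33) and by 1.89 ± 0.35 without the 2 arrays (limma adjusted p = 0.021). Its means of 4.84 in phyb and 3.56 in Col lie below the signal minimum. In limma 11 genes were higher and 16 lower, and 25 of these 27 were among the 58 called without the 2 arrays. A fit of the phyb and Col control arrays alone called no gene. The count of 27 became 3 and 2 without Col control 1 and 2, 4 without phyb control 3 and 15 without phyb control 2. The 58 became 14 to 24 without any Col control array, phyb control 1 or phyb control 3.

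JAZ10 loss by itself gave no called gene in limma in control plants (181 at an unadjusted p under 0.05), and 2 without the doubtful phyb arrays, AT4G31490 (0.66 ± 0.1) and AT3G27240 (-0.81 ± 0.12), both chosen after their values were seen. Without phyb control 2 alone the count was also 2, and most further single omissions from the fit without both arrays gave 0. PDF1.2a differed by 1.57 ± 0.51 (limma adjusted p = 1, n = 2 arrays per group). Without the 2 arrays the jasmonate catabolism list, with a median of 0.743, passed camera (adjusted p = 8.08e-07; adjusted p = 0.0292 with an estimated correlation), which it did not with all arrays (camera adjusted p = 0.182).

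The double mutant also had more PDF1.2a transcript than Col in control plants (3.1 ± 0.51, n = 2 arrays per group), and more of the dehydration genes LTI30 (1.46 ± 0.21, with means of 5.55 and 4.09 below the signal minimum) and KIN2 (0.7 ± 0.11) and the peroxidase PRXCA (0.84 ± 0.15). The abscisic acid and dehydration list, here COR15A, COR47 and KIN2, had a median of 0.639, with 1 member called over all genes and 3 adjusted over the list alone (camera adjusted p = 7.54e-07; adjusted p = 0.00313 with an estimated correlation). The anthocyanin list had a median of -1.01 (camera adjusted p = 5.51e-06; adjusted p = 0.04 with an estimated correlation). The lists for jasmonate catabolism (median 1.1) and photosynthesis (-0.187) passed camera at the preset correlation in both fits. With an estimated correlation they did not pass with all arrays (camera adjusted p = 0.21 and 0.118). Without the 2 doubtful arrays they passed that test too (camera adjusted p = 0.00936 and 0.0435). In limma 7 genes were higher and 6 lower, and 79 in all without the doubtful phyb arrays. The count of 13 became 6 and 4 without Col control 1 and 2, 3 and 4 without jaz10phyb control 1 and 2, and 21 and 22 without phyb control 2 and phyb MeJA 3. The 79 became 24 to 48 without any Col or jaz10phyb control array.

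Effects of phyb and jaz10phyb against the same Col control arrays had a correlation of 0.752 across genes, which are not independent replicates. Unchanged groups simulated against shared controls gave 0.548. The covariance was 0.057 against 0.0228 in the simulation. Called genes overlapped by 1 higher and 5 lower genes, against 0.0135 and 0.0169 for independent lists. Without the 2 doubtful arrays the correlation was 0.688 against 0.503 in the simulation, the covariance 0.0422 against 0.012, and the overlap 14 higher and 14 lower genes against 0.236 and 0.164. Independent lists do not allow for the shared controls.

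The double mutant differed from phyb in control plants by 2 genes in limma, LTI30 (1.32 ± 0.19) and AT1G16850 (1.18 ± 0.18, chosen after its value was seen), and by 9 without the 2 doubtful arrays. The count of 2 changed when any of the 18 arrays was left out, to 3 without either jaz10 control array, 6 without phyb MeJA 3 and 0 or 1 otherwise. The count of 9 fell to between 0 and 5 without any array of Col, jaz10 MeJA or jaz10phyb, phyb control 1 or phyb control 3. The abscisic acid list was higher by a median of 0.438 (camera adjusted p = 2.82e-06; adjusted p = 0.00444 with an estimated correlation). For jasmonate catabolism the median was 0.0248 with all arrays (camera adjusted p = 0.95), and 0.774 without the 2 arrays (camera adjusted p = 3.22e-07; adjusted p = 0.0123 with an estimated correlation). After MeJA limma called no gene (505 at an unadjusted p under 0.05), and 6 were called without the 2 arrays, with JOX4 (1.63 ± 0.19), BSMT1 (1.71 ± 0.23) and the sugar transporter gene SFP1 (0.81 ± 0.11) higher in the double mutant. The count of 0 became 2 and 3 without phyb control 1 and 2. The count of 6 became 0 to 3 without any Col MeJA or jaz10 MeJA array, phyb MeJA 2 or jaz10phyb MeJA 2. The jasmonate catabolism list was higher by a median of 1.77 (camera adjusted p = 0.00283; adjusted p = 0.15 with an estimated correlation), and by 0.746 without the 2 arrays (camera adjusted p = 4.75e-06; adjusted p = 0.0224 with an estimated correlation). The anthocyanin list (0.344; adjusted p = 0.163 with an estimated correlation) and the abscisic acid list (0.19; adjusted p = 0.15 with an estimated correlation, and 0.0224 without the 2 arrays) also passed the preset test.

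The arrays labelled phyb MeJA include the doubtful phyb MeJA 3. Between phyb and Col as labelled, DFR differed by -1.8 ± 0.3 and UGT75C1 by -1.36 ± 0.21 after MeJA. These were the 2 of 4 tested anthocyanin list members called over all genes, with 4 of 4 lower when adjusted over the list alone, and the list had a median of -1.22 (camera adjusted p = 9.5e-06; adjusted p = 0.0775 with an estimated correlation, and 0.0704 without the 2 doubtful arrays; n = 3 phyb and 2 Col arrays). For jasmonate catabolism the median was -1.81 (camera adjusted p = 0.0419; adjusted p = 0.41 with an estimated correlation), and -0.788 without the 2 doubtful arrays (camera adjusted p = 0.000454; adjusted p = 0.0704 with an estimated correlation). CHIL (-1.09 ± 0.21), not a tested member of the anthocyanin list, MT1C, HOS3-1, NGA3 and CLE41 were also lower, and PDF1.2b (2.5 ± 0.44), the shade-responsive HAT2 (0.88 ± 0.17), FDH (0.73 ± 0.14), WLIM1 and AT7SL-1 were higher. Without the 2 doubtful arrays JOX4 (-1.52 ± 0.19) and BSMT1 (-1.46 ± 0.23) were lower too, and BZIP61 (1.79 ± 0.27) and BZIP34 (1.37 ± 0.22) higher. In limma 13 genes were higher and 42 lower, and 160 in all without the 2 arrays. A fit of the phyb and Col MeJA arrays alone called 3 genes. The count of 55 lay between 8 and 34 when any array other than phyb control 1 to 3, phyb MeJA 1 and the jaz10 MeJA arrays was left out, and was 164 without phyb control 2. The 160 became 46, 50 and 23 without Col MeJA 1, Col MeJA 2 and phyb MeJA 2.

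Whether the response itself differed was tested directly. Between phyb and Col, limma called 1 gene, AT3G56260 (-1.49, chosen after its value was seen; 901 genes at an unadjusted p under 0.05), and 4 without the 2 doubtful arrays, among them JOX4 (-1.85 ± 0.26). The median difference for the jasmonate catabolism list was -3.25 with all arrays (camera adjusted p = 0.0122; adjusted p = 0.45 with an estimated correlation) and -1.41 without the 2 (camera adjusted p = 4.6e-06; adjusted p = 0.0409 with an estimated correlation). Between jaz10phyb and Col, limma called 1 gene, AT5G17010 (-0.93), and 6 without the 2 arrays, among them JOX3 (-1.81 ± 0.29). The jasmonate catabolism median differed there by -0.993 (camera adjusted p = 0.281, and 3.08e-05 without the 2 arrays; adjusted p = 0.0612 with an estimated correlation). Over the 3 tested jasmonate catabolism genes the mean difference in response was -1.26, and in control plants jaz10phyb exceeded Col by a mean of 1.22. The control level is a term of the difference in response, so these 2 values are not independent. Without the 2 doubtful arrays, phyb had the same mean difference of -1.26 and exceeded Col in control plants by a mean of 0.381. The Col control signals of these genes lay below the signal minimum. Between jaz10phyb and phyb limma called no gene in either fit (361 and 261 at an unadjusted p under 0.05). The median for jasmonate catabolism differed there by 1.74 (camera adjusted p = 0.0281; adjusted p = 0.289 with an estimated correlation) and by -0.401 without the 2 arrays. The counts of 1 between phyb and Col and between jaz10phyb and Col were each 0 without most other arrays, 4 and 3 without phyb control 2, and for phyb 3 without phyb control 3. Without the 2 doubtful arrays, further single omissions gave 0 to 17 genes for phyb and 0 to 30 for jaz10phyb.

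Genes called and at least 2-fold raised in jaz10, whose arrays enter none of these comparisons, were then followed in the other genotypes. The call also used the spread shared by all groups, so this selection was not independent of the arrays compared. As labelled, these 142 of the 251 raised genes had a median response of 1.51 in Col, 0.322 in phyb and 1.32 in jaz10phyb, and the response was lower in phyb than in Col for 142 of 142 (median difference -1.14, camera p = 7.31e-29; p = 0.135 with an estimated correlation). The phyb median of 0.322 was 0.82 without phyb control 2 and 0.802 without phyb MeJA 3, and between 0.101 and 0.183 without any other phyb array, each with its own selection. Selection by adjusted p alone gave -0.809 over 251 genes, with 243 lower. Without jaz10 control 2 the selection held 23 genes with a median of -0.611, and without any Col or jaz10phyb array 26 to 31 genes with medians between -0.975 and -0.873. Without jaz10 control 1, jaz10 MeJA 1 or jaz10 MeJA 2, limma called 0 raised genes in jaz10 and there was no selection to follow. Without the 2 doubtful arrays, 223 raised genes had medians of 1.61 in Col, 1.23 in phyb and 1.32 in jaz10phyb. The phyb response was lower for 197 of 223 (median difference -0.404, camera p = 7.98e-21; p = 0.0513 with an estimated correlation), and the jaz10phyb response for 173 of 223 (-0.325, camera p = 2.74e-07; p = 0.245 with an estimated correlation). The jaz10phyb response exceeded that of phyb by 0.962 as labelled, by 0.552 without either doubtful array alone, by 0.614 without jaz10 control 2 and by 0.0931 without the 2 arrays (p = 0.32 with an estimated correlation). This last value turned to -0.0113 without phyb MeJA 2. Genes raised at least 2-fold in Col at an unadjusted p under 0.05, the filter of the series text, had a median difference between jaz10phyb and phyb of 0.904 as labelled (246 genes; p = 0.104 with an estimated correlation), 0.472 without phyb control 2 alone, 0.473 without phyb MeJA 3 alone and 0.0589 without the 2 arrays (247 genes; p = 0.558 with an estimated correlation). Across genes, the Col and phyb responses had a correlation of 0.646 as labelled and 0.883 without the 2 arrays, and between 0.131 and 0.334 without phyb MeJA 1, phyb control 1 or phyb control 3. Col and jaz10phyb had 0.834.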

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

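The tests of the phyb array positions and of a weak array, and the omission ranges of phyb minus Col, were chosen only after the results they address were seen.

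The arrays labelled phyb control 2 and phyb MeJA 3 lay with the other treatment. On genes selected in jaz10, where 0 is the mean of the other phyb control arrays and 1 that of the other phyb MeJA arrays, their positions were 1.01 and -0.03. An unequal distribution of signals is argued against, since quantile normalization left the arrays at 1.02 and -0.03. That was no test of an array-wide shift in brightness, which largely cancels between raised and lowered genes. The median signals of the 2 arrays, 16.26 and 16.23, lay within the range of the others. A mixture of both treatments is argued against, since it would place the arrays between 0.25 and 0.75. Exchanged treatment labels may account for the pattern, but on genotype genes the arrays lay at 0.83 and 0.5 against a bound of 0.5, which phyb control 1, an array not in doubt, did not reach (0.45). That axis also moved with treatment, but among MeJA arrays 0.83 lay nearer phyb (0.93 and 0.97) than Col and jaz10 (0.2 to 0.49), among control arrays 0.5 lay within phyb (0.45 and 0.67) and above Col and jaz10 (-0.23 to 0.08), and each array correlated best with a phyb array of the other treatment (0.987 and 0.989); the labels were left as deposited.

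Without these 2 arrays, genes raised by MeJA in jaz10 had a lower median response in phyb than in Col (-0.404, camera p = 7.98e-21; p = 0.0513 with an estimated correlation). Compression at bright signal is argued against, since the dimmer genes differed by -0.407 and the brighter ones by -0.395. A single weak phyb MeJA array may contribute and stays open: the difference stayed below 0 when each array was left out, the closest being -0.293, but the estimated-correlation p there was 0.12, within a range of 0.02 to 0.213. A higher level already in phyb control plants stays open as a part of the difference. Its median was 0.15, between its bounds of 0.1 and 0.2 (0.0433 to 0.231 when each array was left out). Over the same genes phyb minus Col was -0.272 after MeJA (-0.348 to -0.165), a part that the control level does not hold. That median was not tested, and a weak phyb MeJA array would also lower it. An effect of the phyb genotype on the response remains a hypothesis.

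The labelled split of the 6 phyb arrays called 0 genes and the highest of the others 1552, a split that exchanges the 2 doubtful arrays and so points to the structure already described. The 10 splits are too few for a share under 0.05.

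The response to MeJA differed between phyb and Col by a test of the difference for AT3G56260 in both fits (-1.49 with all arrays). Without the 2 arrays it also differed for AT1G08230 (-0.99), AT1G72900 (-1.59) and JOX4 (-1.85). Between jaz10phyb and Col it differed for AT5G17010 in both fits (-0.93 with all arrays). Without the 2 arrays it also differed there for AT1G25230 (1.3), AT3G07730 (-1.54), JOX3 (-1.81), AT3G56260 (-1.25) and AT5G11250 (1.34). The genes without a symbol were chosen after their values were seen. The jasmonate catabolism list differed between phyb and Col by a median of -3.25, and by -1.41 without the 2 arrays, between jaz10phyb and phyb by 1.74 with all arrays, and between jaz10phyb and Col by -0.993 without them. The anthocyanin list differed between jaz10 and Col by 0.531 and the abscisic acid list by -0.369 in both fits. With an estimated correlation, the list difference of -1.41 was the one that passed. For that list without the 2 arrays, phyb minus Col had a mean of 0.381 in control plants and of -0.881 after MeJA. In control plants the jasmonate catabolism list was also higher in jaz10phyb than in Col, by a mean of 1.22.

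Among probe sets with no listed gene, which the comparisons do not use, MeJA in Col changed 672 of 8367 in limma, and 1962 without the 2 doubtful arrays. For MeJA in phyb these counts were 0 and 990.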

How the results depend on the processing

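The omission of the 2 doubtful phyb arrays was chosen after seeing the data. Leaving out 1 array can leave a group with 1 array, which is then assumed to vary like the other groups. Signal over background was not given per probe set, so weak genes are limited by the signal minimum alone. Other probe sets of the named genes gave no value, because none has another. The cause of the changes was not tested except where fewer arrays or more genes tested are the setting itself. Counts for unadjusted p and for the SAM-type statistic also required a 2-fold change. The SAM-type null pooled all 6 relabellings of the Col arrays, among them the labelling itself and its mirror. That caps how many genes can reach a SAM-type p under 0.05 (838 did before the 2-fold minimum). Its count of 358 is therefore no independent check. Counts of genes follow, with the reported value first.

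For MeJA in Col (837), no filter gave 214, both arrays left out 1771, a separate fit 1502, unadjusted p with 2-fold 372 and the SAM-type statistic 358, and omission of each array 0 to 1417 (1119 to 1781 after both were left out). For MeJA in phyb (0), no filter gave 1, both left out 926 and unadjusted p 1, and omission of each array 0 (402 to 1040). For MeJA in jaz10 (497), no filter gave 127, all probe sets 233, both left out 1400 and a separate fit 1244, and omission of each array 0 to 1026 (801 to 1419). For MeJA in jaz10phyb (2), no filter and all probe sets gave 0, the stricter filter 15, trend 10, both left out 1058, a separate fit 842 and unadjusted p 239, and omission of each array 0 to 547 (635 to 1077).

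For phyb against Col in control (27), all probe sets gave 47, both left out 58, a separate fit 0 and unadjusted p 41, and omission of each array 2 to 38 (14 to 63). For jaz10 against Col (0), the stricter filter, trend and unadjusted p gave 1, all probe sets and both left out 2, and omission of each array 0 to 2 (0 to 1). For jaz10phyb against Col (13), trend gave 20, all probe sets 26, centring 21, both left out 79, a separate fit 63 and unadjusted p 30, and omission of each array 3 to 22 (24 to 93). For jaz10phyb against phyb in control (2), no filter, the stricter filter, quantile normalization and a separate fit gave 0, all probe sets 1, both left out 9 and unadjusted p 5, and omission of each array 0 to 6 (0 to 10). For phyb against Col in MeJA (55), no filter gave 34, all probe sets 85, both left out 160 and a separate fit 3, and omission of each array 8 to 164 (23 to 182). For jaz10phyb against phyb in MeJA (0), trend gave 3, all probe sets and quantile normalization 2, both left out 6 and unadjusted p 18, and omission of each array 0 to 3 (0 to 8).

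For the response in phyb against Col (1), no filter, the stricter filter, centring and a separate fit gave 0, trend 2, both left out 4 and unadjusted p 182, and omission of each array 0 to 4 (0 to 17). For jaz10 against Col (0), unadjusted p gave 19, and omission after both 0 to 1. For jaz10phyb against Col (1), both filters, trend and all probe sets gave 0, both left out 6, a separate fit 17 and unadjusted p 29, and omission of each array 0 to 3 (0 to 30). For jaz10phyb against phyb (0), unadjusted p gave 44.

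Arrays with the same replicate number had correlations of deviations of 0.094 in Col, -0.019 in jaz10, 0.1 in jaz10phyb, and -0.721, 0.452 and 0.602 in phyb, where pairs 2 and 3 each hold a doubtful array. Both phyb group means, from which deviations were taken, include a doubtful array, so the -0.721 of pair 1 depends on these arrays too. The numbers were not taken as pairs. As a block they gave 923 genes for MeJA in jaz10, 392 in jaz10phyb, 58 for phyb against Col in control, 5 for jaz10phyb against phyb in control, 24 for phyb against Col in MeJA, 0 for the responses of phyb and jaz10phyb against Col, and a median of 0.0982 for genes lowered in jaz10 (jaz10phyb against Col).

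Median differences in response between jaz10phyb and phyb turned sign when both arrays were left out: from -0.582 to 0.0916 for genes lowered in Col, from -0.666 to 0.00341 for genes lowered in jaz10, and from 1.74 to -0.401 for the jasmonate catabolism list. Between jaz10phyb and Col, both left out gave -0.325 for genes raised and 0.108 for genes lowered in jaz10, past the test at a preset correlation but not at an estimated one (p = 0.245 and 0.202). Omission of an array gave -0.297 to 0.23 for the latter, and -0.862 to -0.302 between jaz10phyb and phyb, over 15 arrays: without jaz10 control 1, MeJA 1 or MeJA 2 the call in jaz10 left no selection. After both were left out, omission gave -0.0622 to 0.166 (raised in Col), -0.0928 to 0.286 (lowered in Col), -0.0113 to 0.188 (raised in jaz10) and -0.134 to 0.12 (lowered in jaz10) between jaz10phyb and phyb, so that no direction of this difference held.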

Other observations

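Some genes without a symbol, chosen here after their values were seen, were lower in control plants of both mutants that lack phytochrome B. AT3G55920 had a mean log2 signal of 7.02 ± 0.02 (SD, n = 2) in Col control plants, 3.77 ± 0.42 (n = 3) in phyb and 3.94 ± 0.5 (n = 2) in jaz10phyb, a difference of -3.25 between phyb and Col (limma adjusted p = 8.1e-06) whose size is uncertain, since the mutant means lie below the signal minimum of 5.67. AT4G13575 had means of 8.16, 5.92 and 6 (-2.24, limma adjusted p = 0.00015) and AT3G46370 of 6.87, 5.33 and 5.28, the last 2 also below that minimum (-1.55, limma adjusted p = 0.023). All 3 differences passed again without the 2 doubtful arrays, at -3.44, -2.3 and -1.35.

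Gene families grouped by symbol and the 63 plastid-encoded genes were defined after the annotation was seen. Members of the TBL family, 10 genes of wall polysaccharide acetylation, had a median response to MeJA of 0.307 in jaz10, with 2 called (camera adjusted p = 0.0384; adjusted p = 0.633 with an estimated correlation). Across 18 such groups and 14 contrasts with all arrays, 6 tests passed with the preset correlation, and those 6 did not pass with an estimated one.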
